A study of Mus musculus with 8 samples.

How the data were processed

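Total RNA of mouse 3T3-L1 cells was measured on 8 one-colour arrays, 2 for each of 4 groups: control and knockdown supernatant after 3 h and after 6 h. Per the labels' protocols, the cells grew in 10% fetal calf serum before differentiation, and 0.1 ug RNA per sample was labelled with the dye Cy3. The labels call the arrays biological replicates and do not say whether wells shared a supernatant preparation, so p-values measure only the spread between these samples. Groups and replicate numbers came from the sample labels. The authors' deposited scanner output gives for each spot a processed signal, which is a background-subtracted and detrended intensity on a linear scale not scaled between arrays, per the file headers. It was made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Median spot and median local background intensity per spot were deposited too and were used for a background alternative. A deposited value table of the same arrays holds log2 values. Set against the scanner values it equalled the log2 processed signal with 1 shift per array (correlation 1.00) and was not centred per gene, with medians of -4.14 and -4.17 on the control and -4.22 and -4.23 on the knockdown 3 h arrays, and -3.95, -4.05, -4.11 and -4.22 at 6 h. It was used as an alternative.

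Each array had 59305 non-control spots, 0 of them saturated, and 163 to 319 spots marked as outliers by the scanner software were left out. Log2 processed signals were scaled by subtracting each array's 75th percentile, and spots of 1 probe were averaged. Of 55681 probes, 27235 were named through their RefSeq transcript and 20 by symbol or synonym, using RefSeq names of assembly GRCm38.p6 for names only, and 28426 stayed unnamed and were tested as probes. A probe entered if well above background on both arrays of at least 1 group, which 30113 did. The probe with the highest mean represented each gene, leaving 25799 genes and unnamed probes, 13785 of them named. Of 3594 genes with over 1 tested probe, 117 were called for the average, and 6 of these had a probe in the other direction. The number of arrays limits the precision. All lay on 1 slide scanned once.

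A model of 4 group means was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with 4 residual and 1.74 prior degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes and probes tested in a comparison. Genes passed at an adjusted p under 0.05. Errors are standard errors of that model, which gives each gene 1 spread shared by all 8 arrays. The comparisons were knockdown minus control at 3 h, at 6 h and averaged, the difference of these effects, and 6 h minus 3 h in each supernatant. Where a gene was not well above background on any array of a group, its change is given as at least N-fold. This sets the brighter group's mean against the dim group's mean of, per array, the higher of its own signal and the lowest signal among probes well above background. No fold is given where no compared array was above background, where this leaves no bound over 1 or where only part of the averaged groups was above background. Overlaps expected within groups of 100 genes of like residual variance were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

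The gene lists, tests, rule for named genes and alternatives, apart from a masking of bright patches and list tests beyond those of the supernatants and of time with control supernatant, were fixed before the data were examined. The 26 lists were immediate early genes, acute phase and IL-6/STAT3 response, NF-kB and TNF response, TGF-beta and extracellular matrix, chemokines, interferon response, adipokines, matrix proteases, prostaglandin synthesis and nitric oxide, glucocorticoid response, heat shock, cholesterol synthesis, lipolysis and fatty acid oxidation, fatty acid and triglyceride synthesis, insulin signalling, hypoxia and glycolysis, oxidative phosphorylation, oxidative stress, unfolded protein response, circadian clock, cell cycle, ribosomal proteins, adipocyte identity and PPARG targets, and markers of preadipocytes and fibroblasts, of macrophages and leukocytes, and of endothelial and muscle cells. Of 829 entries 828 matched a symbol, and some genes stood in several lists. Lists with at least 5 tested members were tested with camera in limma at a preset correlation of 0.01, with an estimated correlation and with fry beside it. A call lost with the estimate need not reflect a higher correlation. For heat shock at 6 h the estimate was -0.017, under the preset, yet the camera p before adjustment rose from 0.00799 to 0.0423. Named genes were the up to 10 largest calls in each direction whose arrays did not overlap between groups (up to 5 for time and the difference of effects), up to 4 members per list with the smallest p (up to 3 for time), and further genes chosen beforehand, among them Usp2, Fabp4, Adipoq, Il6, Ccl2, Saa3 and Lcn2.

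The fit was tested on simulated data with 200 changed genes among 25715. At 3 h it recovered 17.9% of genes changed 1.5-fold, 68.7% of those changed 2-fold and 97.0% of those changed 4-fold, and at 6 h 17.9%, 68.7% and 93.9%. For the average it recovered 68.7%, 82.1% and 100% and for the difference of effects 1.49%, 34.3% and 87.9%. Between 0.0196% and 0.0431% of unchanged genes were called. The simulated noise was independent between genes, had the same spread in all groups and held no bright patches. In the data the SD of the log2 difference between replicates was 0.23 for knockdown at 3 h and 0.53 for control at 6 h. These rates therefore hold for the simulated setting and may differ in the data. With 1 list shifted, that list was recovered and 3 of 26 lists were called, some sharing members.

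Alternatives were normexp background correction (offset 50), quantile normalization, median scaling and no scaling, no filter and a filter on all 8 arrays, the mean of a gene's probes and each probe alone, eBayes with trend and robust options, array weights, the arrays of 1 time alone, the replicate number as a block, the deposited log2 table, an adjusted p of 0.10, a minimum of 1.5-fold, other list tests, and leaving out each array. A spot lay in a bright patch of an array where its neighbours in a square window of 7 spots a side had a median log2 excess over 0.5 above the median of the 8 arrays, or where over 30% of them had an excess over 1; masking set such spots to missing.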

Results

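Mouse 3T3-L1 cells, a fibroblast line that can be turned into fat-like cells, were kept in adipogenic medium for 1 week and then given supernatant of human HL-60 leukemia cells. The HL-60 cells had been driven towards a macrophage-like state with 30 nM of the phorbol ester PMA for 5 days. In one arm USP2, a ubiquitin-specific protease, had been knocked down in the HL-60 cells, and in the other arm they carried a mock vector. The supernatants were diluted 2-fold, and total RNA of the 3T3-L1 cells was taken after 3 h or 6 h. Each of the 4 groups held 2 arrays, described by the submitters as biological replicates, so 8 one-colour arrays were compared and this number limits the precision. On their slide, control arrays lay in columns 1 and 2 and knockdown arrays in columns 3 and 4, so supernatant and slide column cannot be told apart. The question was which transcripts of the 3T3-L1 cells differed with the supernatant of USP2 knockdown cells (KD in the plots) against that of control cells. Between 50.7% and 55.9% of the 59305 non-control spots were well above background on each array, and the 75th percentile of the signal lay between 478 and 621. Replicate arrays correlated across genes at 0.997 and 0.998 in the control and knockdown groups at 3 h, and at 0.988 and 0.993 at 6 h. The first principal component held 61.5% of the variance and separated 3 h from 6 h, and the second held 14.5%.

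The knockdown was made in the human cells, so mouse Usp2 in the 3T3-L1 cells does not check it. Relative to the array's 75th percentile, the log2 signal of Usp2 was -2.86 and -2.73 on the control arrays and -2.56 and -2.76 on the knockdown arrays at 3 h. At 6 h it was -3.17 and -3.03 against -3.17 and -3.04. Usp2 did not pass at either time, with log2 fold changes of 0.13 ± 0.11 (SE, 2 arrays per group; limma adjusted p = 0.772) and -0.0039 ± 0.11 (adjusted p = 0.987). Of the adipocyte markers, Pparg, Fabp4, Lpl and Fabp5 were well above background on all 8 arrays, as were 23 of the 40 listed. Adipoq, Cidec, Cd36, Lep, Cfd, Adrb3, Car3, Slc2a4, Pck1, Klb and Trarg1 were not well above background on any of the 8 arrays. Of 27 preadipocyte and fibroblast markers, 26 were well above background on all 8 arrays, among them Dlk1, Thy1, Vim and Col1a1, and Sfrp1 was on none. Of the markers of other cells, 7 of 26 macrophage and leukocyte genes and 10 of 20 endothelial and muscle genes were on none.

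After 3 h, cells given knockdown supernatant held more transcript of several secreted and signalling genes. Serpinb2, which encodes a plasminogen activator inhibitor, was higher by 1.94 ± 0.12 on the log2 scale (SE, 2 arrays per group; adjusted p = 0.0162), and the cytokine gene Il6 by 1.66 ± 0.090 (adjusted p = 0.0124). Id3, an inhibitor of helix-loop-helix factors, was higher by 1.46 ± 0.067, and Inhba, a subunit of activin, by 1.21 ± 0.057. Higher too were the mRNA-destabilising factor Zfp36 with 1.39 ± 0.13, the serpin Serpina3f with 1.37 ± 0.092, the protease gene Mmp10 with 1.32 ± 0.1 and the growth factor gene Ccn2 with 1.26 ± 0.086. The feedback inhibitor of cytokine signalling Socs3 was higher by 1.25 ± 0.082 and the nuclear receptor Nr4a1 by 1.19 ± 0.12. The secreted metalloprotease Adamts15 fell by 1.63 ± 0.090 (adjusted p = 0.0124), Foxo6 fell by 0.91 ± 0.096 and Rab3a fell by 0.63 ± 0.060. Kcne1 was at least 3.05-fold lower (adjusted p = 0.0351), because it was not well above background on either knockdown array. Slc25a29 did not pass (log2 fold change -0.65, adjusted p = 0.0518). With limma, 63 of 25799 genes and unnamed probes passed, 58 higher and 5 lower, of which 47 and 4 had gene names. Each of the 27 genes named by rule that passed at 3 h missed the threshold without 1 array or more, with Il6, Id3 and Adamts15 at an adjusted p up to 0.191 and Serpinb2 up to 0.236.

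Among the gene groups at 3 h, the immediate early genes, transcribed within minutes to hours of a stimulus, were higher as a group. Of 38 members, 9 were higher and 0 lower over all genes, and 26 were higher adjusted over the list alone (median log2 fold change 0.60; camera adjusted p = 2.14e-31). The growth factors Hbegf (1.17 ± 0.078) and Ereg (1.12 ± 0.070), the phosphatase gene Dusp4 (0.78 ± 0.063) and Fos (0.95 ± 0.079) were among them. Of 25 acute phase and IL-6/STAT3 response genes, 5 were higher, 15 adjusted over the list alone (median 0.43; camera adjusted p = 2.29e-17). They included the serum amyloid gene Saa3 with 0.80 ± 0.061 and the transcription factor Cebpd with 1.10 ± 0.085. Of 30 NF-kB and TNF response genes, 3 were higher, 16 adjusted over the list alone (median 0.29; camera adjusted p = 2.46e-18). These were Il6, the endoribonuclease Zc3h12a (1.08 ± 0.057) and the chemokine Cxcl1 (0.82 ± 0.082), while Ccl2 did not pass (0.56 ± 0.087, adjusted p = 0.0946). Of 39 TGF-beta and extracellular matrix genes, 5 were higher, 13 adjusted over the list alone (median 0.14; camera adjusted p = 2.48e-11). Id3, Ccn2, Ccn1 (0.90 ± 0.075) and Id1 (0.68 ± 0.064) were among them. Col1a1 and Fn1, singled out after their values were seen, did not pass (0.093 and -0.087, adjusted p = 0.835 and 0.921). These 4 lists also passed with an estimated correlation, at adjusted p = 0.0269, 0.0163, 0.0269 and 0.0269 in the order given.

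Another 6 lists passed camera at 3 h with the preset correlation and lost the call with an estimated one. Their estimates lay between 0.014 for lipolysis and fatty acid oxidation and 0.25 for adipokines, against the preset 0.01. Of 19 adipokines, 3 were higher and 8 adjusted over the list alone (camera adjusted p = 8.84e-08; adjusted p = 0.17 with an estimated correlation). Those 3 were Il6, Saa3 and Angptl4, an inhibitor of lipoprotein lipase (0.64 ± 0.068), while Lcn2 did not pass (0.11 ± 0.097). Of 38 interferon response genes 0 passed in limma and 4 were higher adjusted over the list alone (median 0.10; camera adjusted p = 6.27e-06; adjusted p = 0.17 with an estimated correlation), with Rsad2 at 0.53 ± 0.065 and Cxcl10 at 0.77 ± 0.12. Of 27 matrix proteases and their inhibitors, Mmp10 was higher and 7 were higher adjusted over the list alone (camera adjusted p = 0.000309; adjusted p = 0.135 with an estimated correlation). The lipolysis and fatty acid oxidation list was lower (median -0.12; camera adjusted p = 0.00214; adjusted p = 0.135 with an estimated correlation). None of its 27 members passed, 0 over all genes and 0 adjusted over the list alone; Ppargc1a measured -0.85 ± 0.2 and G0s2 -1.16 ± 0.32, G0s2 with 1 of 2 knockdown arrays well above background. Of 18 chemokines, 1 was higher and 6 adjusted over the list alone, with a median just above 0 that turned just below it with no scaling (camera adjusted p = 0.00214; adjusted p = 0.354 with an estimated correlation). Of 26 glucocorticoid response genes, 3 were higher, with 5 higher and 1 lower adjusted over the list alone, and its median turned below 0 with no scaling (camera adjusted p = 0.00997; adjusted p = 0.17 with an estimated correlation). They included Errfi1 (0.60 ± 0.059). The prostaglandin synthase gene Ptgs2 was higher by 1.18 ± 0.092, in a list that did not pass at 3 h (camera adjusted p = 0.238). The limma gene count at 3 h was 0 without control 3 h replicate 1, without any 1 of the 4 knockdown arrays, or with the 4 arrays of 3 h alone, against 1640 to 3574 at an unadjusted p under 0.05. It was 2 without control 3 h replicate 2 and 35 without either control 6 h array. Without control 3 h replicate 2 the chemokines lost their call (camera adjusted p = 0.0642), and without knockdown 3 h replicate 1 the glucocorticoid list did (camera adjusted p = 0.159).

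**Figure D1:**
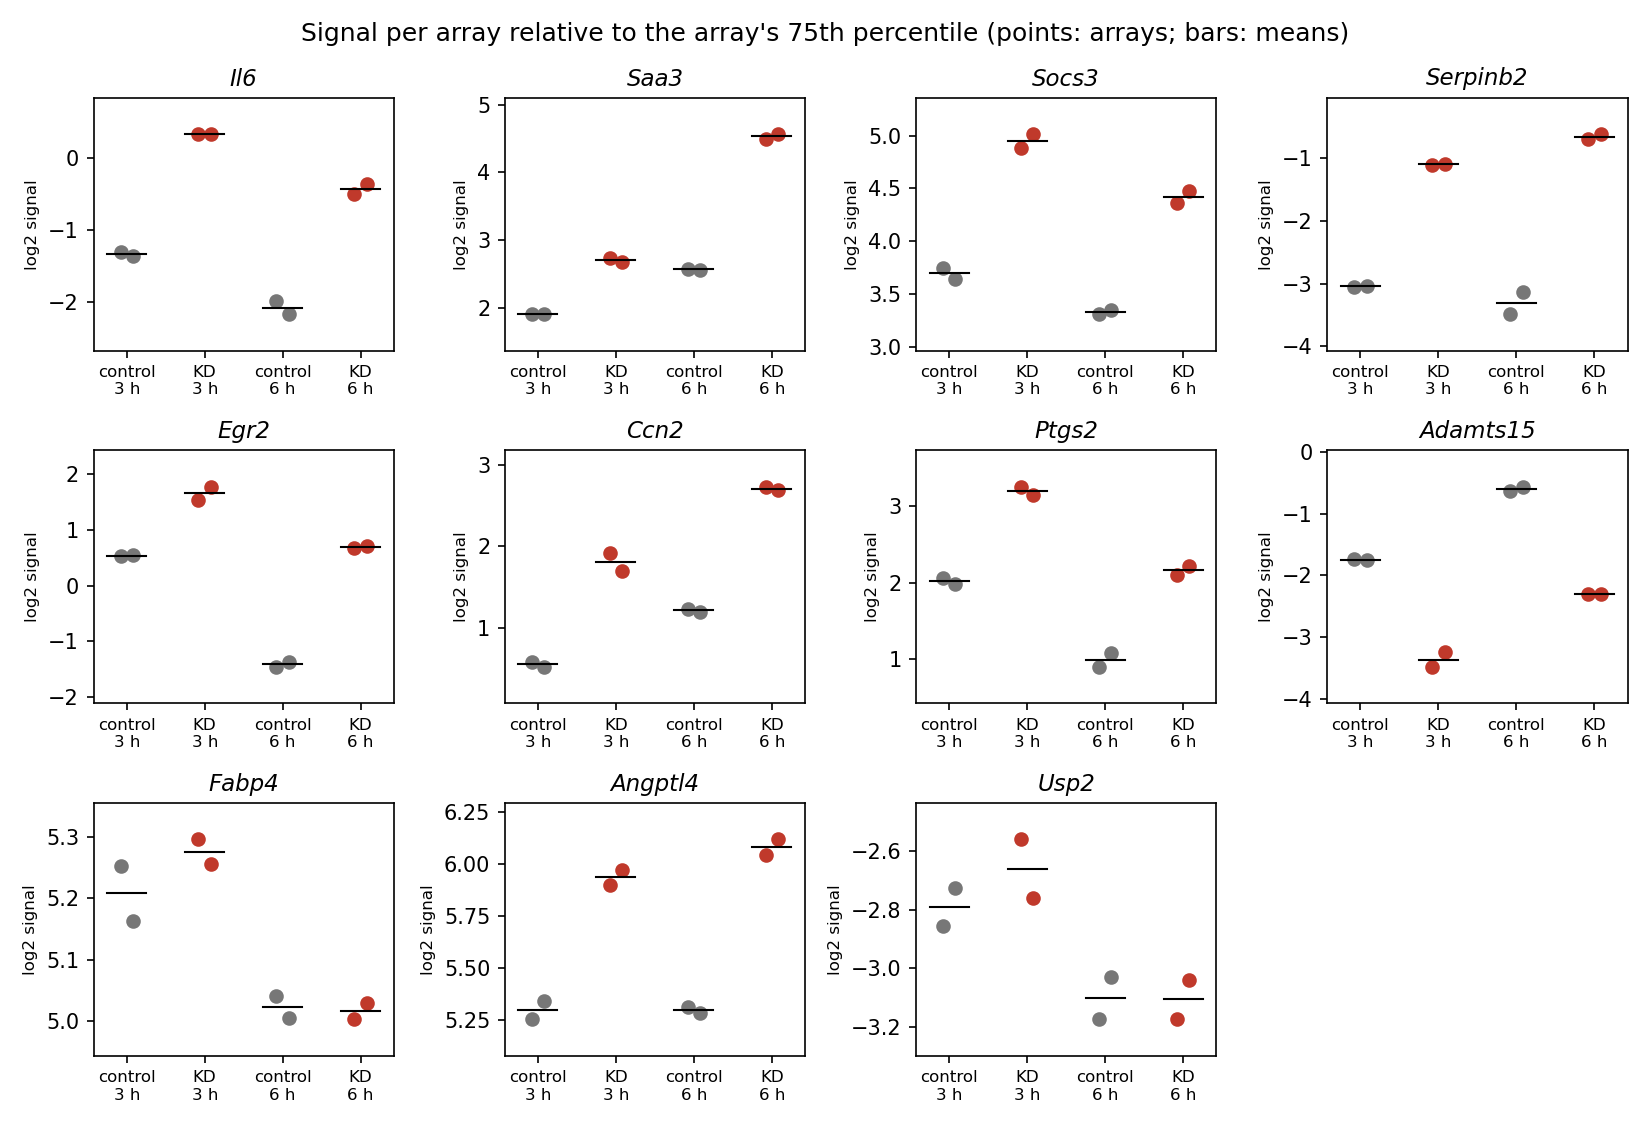
Log2 signal relative to the array's 75th percentile (vertical axis) of 11 genes in the 4 groups; points are single arrays, horizontal bars are means of 2 arrays, grey is control and red is knockdown supernatant (KD). Both KD arrays of Il6, Saa3, Socs3, Serpinb2, Egr2, Ccn2 and Ptgs2 lie above both control arrays of the same time, those of Adamts15 lie below, and the arrays of Usp2 overlap.

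After 6 h with knockdown supernatant, acute phase genes were among those called. Saa3 was higher by 1.96 ± 0.061 on the log2 scale (SE, 2 arrays per group; adjusted p = 0.00278), haptoglobin (Hp) by 1.72 ± 0.067 and Saa1 by 1.62 ± 0.1. Serpinb2 was higher by 2.66 ± 0.12 (adjusted p = 0.00343), Mmp10 by 2.15 ± 0.1, the zinc finger factor Egr2 by 2.09 ± 0.094 and Serpina3f by 2.08 ± 0.092. Il6 was higher by 1.64 ± 0.090 (adjusted p = 0.00401). The transcription factor gene Npas4 was higher by 2.31 ± 0.18, with 1 of 2 control arrays well above background. The channel gene Kcnj12 passed as higher with 0 of 2 control and 1 of 2 knockdown arrays above background, and no fold is given because its bound was not over 1. Trhr2, Prss46 and Efcab6 were at least 3.72-fold, 2.73-fold and 1.04-fold higher, since neither control array was well above background. Adamts15 fell by 1.71 ± 0.090 (adjusted p = 0.00395). Lhx3, Slc34a1 and Gask1a were at least 3.31-fold, 2.95-fold and 2.37-fold lower, since neither knockdown array was well above background. Rtn4r passed with no array at 6 h well above background, so no fold is given.

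The 5 named genes that fell at least 4-fold at 6 h lay in bright patches of the control arrays, areas where neighbouring spots were raised together. Kiss1 and Olfr509 were at least 35.6-fold and 8.14-fold lower, with spots inside a patch on both control 6 h arrays, so that no control value was left at 6 h outside patches. Guca1a, Ano2 and Olfr67 were at least 8.4-fold, 5.35-fold and 4.95-fold lower, with a spot inside a patch on 1 of them. With patches set to missing, a setting added after the data were seen, Guca1a no longer passed (adjusted p = 0.0533), while Ano2 and Olfr67 did (adjusted p = 0.00620 and 0.00588). Patches covered 2.47% and 3.95% of spots on the control 6 h arrays, 2.24% and 0.376% on the knockdown 6 h arrays and at most 0.155% on each 3 h array. Il6 and Adamts15 each had 1 compared array in a patch, and with patches set to missing they measured 1.57 and -1.75 (adjusted p = 0.00622 and 0.00824). At 6 h 593 genes and unnamed probes passed in limma, 413 higher and 180 lower, of which 295 and 106 had gene names. That count rests on the shared spread, though replicates differed most in control at 6 h. With array weights, 0.475 for each control 6 h array and 1.52 for each knockdown 3 h array, 194 passed at 6 h and 310 at 3 h. Of the 593, 94 were not well above background in a compared group. With each array's median in place of its 75th percentile the split was 967 higher and 108 lower, and with no scaling 51 and 45. Only 50.7% to 55.9% of spots per array were well above background, so an array's median lies near the background limit.

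Of 25 acute phase and IL-6/STAT3 response genes, 16 were higher at 6 h and 20 adjusted over the list alone. The median log2 fold change was 0.70 (camera adjusted p = 4.34e-19), and the call held with an estimated correlation (adjusted p = 0.0128). Cebpd (1.22 ± 0.085) and Socs3 (1.09 ± 0.082) were among them, and Lcn2, a siderophore-binding protein, measured 0.64 ± 0.097 (adjusted p = 0.0379). Of 38 immediate early genes, 16 were higher, and 25 were higher and 1 lower adjusted over the list alone (median 0.60; camera adjusted p = 2.39e-16; adjusted p = 0.0793 with an estimated correlation). Egr2, Ereg (1.37 ± 0.070), Dusp4 (0.98 ± 0.063) and Dusp6 (1.45 ± 0.098) were among them. Of 30 NF-kB and TNF response genes, 11 were higher, and 23 were higher and 1 lower adjusted over the list alone (median 0.40; camera adjusted p = 7.38e-14; adjusted p = 0.0706 with an estimated correlation). Ccl2, a monocyte-attracting chemokine, was higher by 1.10 ± 0.087, Bcl3 by 0.86 ± 0.067 and Zc3h12a by 0.66 ± 0.057. Of 39 TGF-beta and extracellular matrix genes, 11 were higher, and 14 were higher and 2 lower adjusted over the list alone (median 0.17; camera adjusted p = 3.23e-06; adjusted p = 0.0844 with an estimated correlation). They included Ccn2 (1.49 ± 0.086), Id3 (1.04 ± 0.067), Id1 (0.90 ± 0.064) and Pmepa1 (0.87 ± 0.063).

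Of 19 adipokines, 6 were higher at 6 h and 8 adjusted over the list alone (camera adjusted p = 9.63e-05; adjusted p = 0.322 with an estimated correlation). Angptl4 was higher by 0.78 ± 0.068. Of 27 matrix proteases and inhibitors, 6 were higher, and 12 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.00226; adjusted p = 0.196 with an estimated correlation). Besides Mmp10, the urokinase receptor gene Plaur (1.29 ± 0.088) and Adamts4 (0.61 ± 0.060) passed. Of 19 prostaglandin and nitric oxide genes, 2 were higher, and 9 were higher and 3 lower adjusted over the list alone (camera adjusted p = 0.018; adjusted p = 0.391 with an estimated correlation). These were Ptgs2 (1.18 ± 0.092) and Gch1 (0.77 ± 0.11), a gene of tetrahydrobiopterin synthesis. Of 18 chemokines, 3 were higher, 6 adjusted over the list alone (camera adjusted p = 0.0311; adjusted p = 0.567 with an estimated correlation): Ccl2, Cxcl10 (0.74 ± 0.12) and Ccl7 (0.54 ± 0.061). At 6 h the 8 spike-in transcripts had a median of 0.15 (SD 0.10). The heat shock and cholesterol synthesis lists passed camera as higher with smaller medians, 0.094 and 0.062 (adjusted p = 0.026 and 0.0409, and 0.196 and 0.322 with an estimated correlation). None of their 24 and 26 members passed in limma, 0 in each over all genes and 0 adjusted over the list alone. The limma gene count at 6 h was 220 without either control 3 h array, 147 without either knockdown 3 h array, and 144 and 356 without knockdown 6 h replicate 1 and 2. Without either control 6 h array the excess of higher over lower calls was lost or nearly so. The lone control 6 h array left was then assumed to vary like the other groups, so these fits cannot decide on that excess. With bright patches masked 488 were higher and 195 lower. With the 4 arrays of 6 h alone the limma gene count was 0, against 3044 at an unadjusted p under 0.05. Of 48 genes named by rule that passed, 21 missed the threshold without 1 array or more, at adjusted p up to 0.178 (Cxcl10), among them Angptl4, Lcn2, Zc3h12a, Ccl7, Gch1, Adamts4, Npas4, Kcnj12, Trhr2, Prss46, Kiss1, Guca1a, Ano2, Olfr67, Slc34a1, Lhx3, Plin4, Dbp and Zfp423. The heat shock, cholesterol, prostaglandin and chemokine calls were each lost without 1 array of 6 h or more, with camera adjusted p of 0.101, 0.205, 0.0797 and 0.103 without knockdown 6 h replicate 2. Without control 6 h replicate 1 the first 3 were at 0.123, 0.123 and 0.105, and without control 6 h replicate 2 the cholesterol and chemokine lists were at 0.0617 and 0.121.

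**Figure D2:**
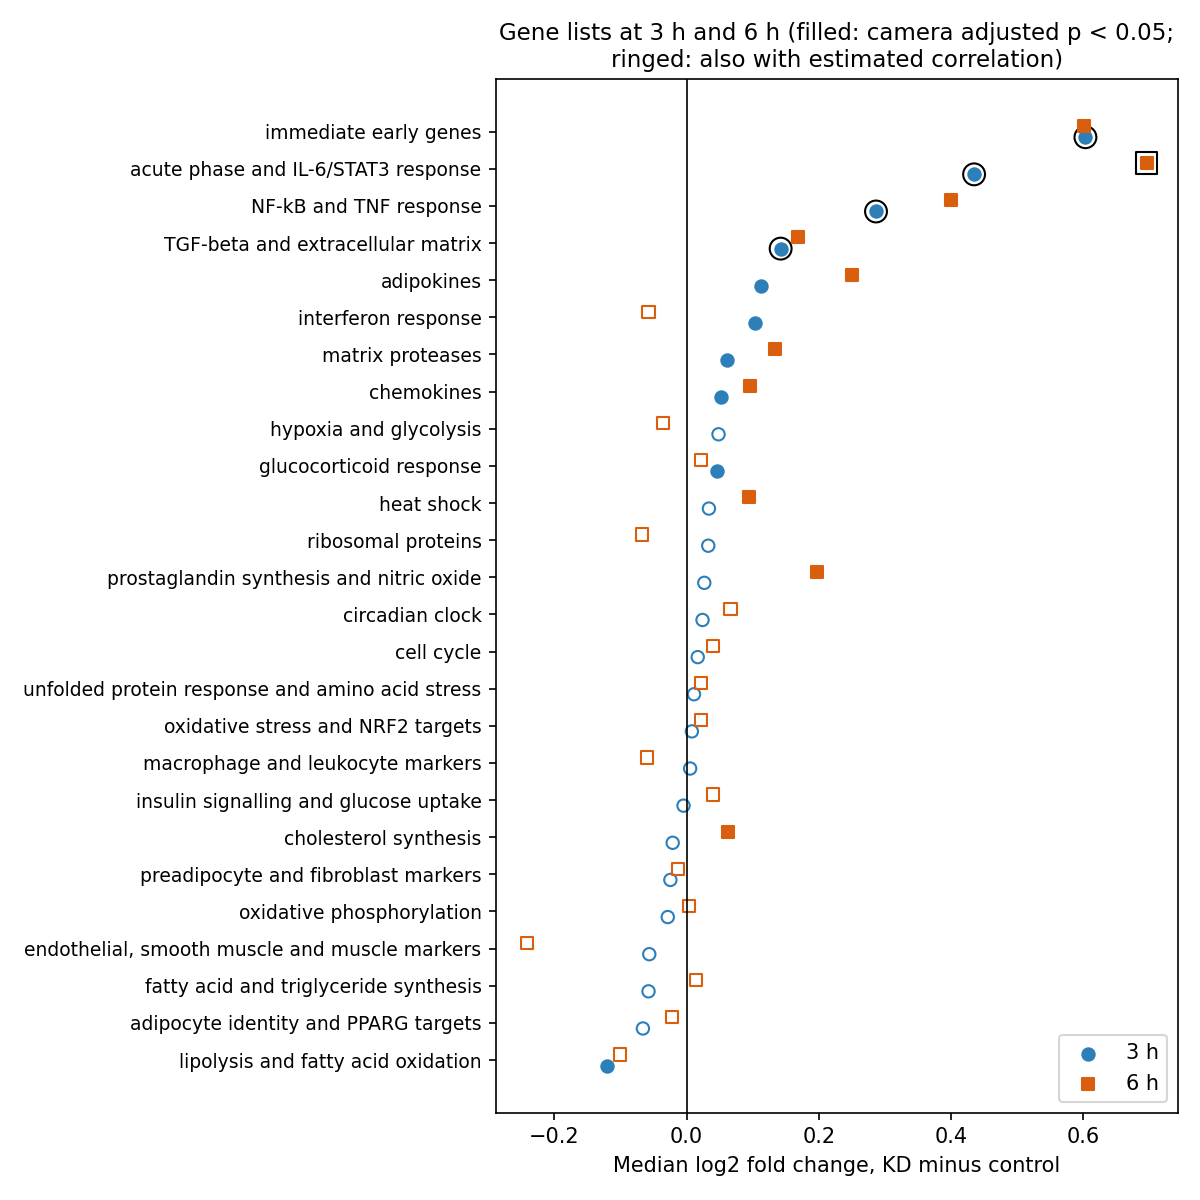
Median log2 fold change, knockdown (KD) minus control supernatant (horizontal axis), over the tested members of each of the 26 gene lists at 3 h (circles) and 6 h (squares); filled symbols passed camera with the preset correlation and ringed ones also with an estimated correlation. The medians of the immediate early, acute phase, NF-kB and TGF-beta lists lie between 0.14 and 0.70 at the 2 times.

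Averaged over both times, with 4 knockdown and 4 control arrays, Serpinb2 was higher by 2.30 ± 0.086 on the log2 scale (SE, 4 arrays per supernatant; adjusted p = 0.00139), Mmp10 by 1.73 ± 0.073, Serpina3f by 1.72 ± 0.065 and Il6 by 1.65 ± 0.064 (adjusted p = 0.00139). Egr2 was higher by 1.60 ± 0.067, the G protein regulator Rgs16 by 1.53 ± 0.071, Npas4 by 1.86 ± 0.13 and Saa3 by 1.38 ± 0.043. Prss46 and Kcnj12 were at least 1.74-fold and 1.46-fold higher. Trhr2 passed as higher with only the knockdown 6 h arrays well above background, so no fold is given. Adamts15 fell by 1.67 ± 0.064 (adjusted p = 0.00139), Grpr, a receptor for gastrin-releasing peptide, fell by 0.94 ± 0.070, Clec14a fell by 0.95 ± 0.11 and Smad9 fell by 0.96 ± 0.098, Smad9 with 3 of 4 knockdown arrays well above background. Otop1, Rtn4r and Lhx3 passed as lower (adjusted p = 0.0147, 0.0063 and 0.0162), and no fold is given because neither knockdown 6 h array was well above background. Kiss1 and Ano2, in bright patches at 6 h, passed as lower with only the control 6 h arrays well above background, so no fold is given. Kcne1 was at least 1.42-fold lower, with 1 compared array in a bright patch. Setting patches to missing left its fitted value unchanged, so its call there (limma adjusted p = 0.0151) is no check on the patch. In limma 807 genes and unnamed probes passed, 558 higher and 249 lower, of which 398 and 157 had gene names, and 52 and 30 changed at least 2-fold. The share of higher calls, 69.1%, was 91.2% with median scaling and 68.6% with bright patches masked. It was lower without either control 6 h array, where the lone array left was assumed to vary like the other groups.

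Of the immediate early genes 20 of 38 were higher, 30 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 1.45e-25). Of the acute phase genes 15 of 25 were higher, 20 adjusted over the list alone, with a median of 0.53 (camera adjusted p = 3.66e-20). Of the NF-kB and TNF response genes 18 of 30 were higher, and 23 were higher and 2 lower adjusted over the list alone (median 0.36; camera adjusted p = 7.55e-18). Of the TGF-beta and matrix genes 11 of 39 were higher, and 18 were higher and 1 lower adjusted over the list alone (median 0.16; camera adjusted p = 1.43e-08). All 4 passed with an estimated correlation too (adjusted p = 0.0341, 0.0119, 0.0341 and 0.0461). Ccl2 measured 0.83 ± 0.062, Hp 1.20 ± 0.048, Socs3 1.17 ± 0.058, Id3 1.25 ± 0.047 and Ptgs2 1.18 ± 0.065, and all 5 passed. Adipokines (7 of 19 higher, 9 adjusted over the list alone), matrix proteases (6 of 27; 10 higher and 1 lower adjusted over the list alone) and chemokines (6 of 18; 6 higher and 1 lower adjusted over the list alone) passed camera as higher. Their camera adjusted p were 1.21e-06, 0.000398 and 0.00774 (adjusted p = 0.242, 0.138 and 0.451 with an estimated correlation). The lipolysis and fatty acid oxidation list was lower (median -0.088, 0.042 with median scaling; camera adjusted p = 0.00513; adjusted p = 0.138 with an estimated correlation). Its member Mgll, a monoglyceride lipase, fell by 0.28 ± 0.048, and 3 members were lower adjusted over the list alone. The heat shock list passed camera as higher with a median of 0.082 (adjusted p = 0.013, and 0.138 with an estimated correlation). Of its 24 members 0 passed in limma, and 0 adjusted over the list alone. The prostaglandin and nitric oxide list passed camera as higher too (adjusted p = 0.0282, and 0.451 with an estimated correlation). Of its 19 members 4 were higher and 2 lower, 8 and 2 adjusted over the list alone.

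The other 16 lists did not pass camera for the average. Their adjusted p were 0.0617 for glucocorticoid response, 0.17 for interferon response, 0.17 for cholesterol synthesis, 0.177 for endothelial and muscle markers, 0.374 for the circadian clock, 0.449 for preadipocyte and fibroblast markers and 0.476 for adipocyte identity and PPARG targets. They were 0.476 for the cell cycle, 0.477 for ribosomal proteins, 0.6 for hypoxia and glycolysis, 0.608 for insulin signalling, 0.608 for oxidative phosphorylation, 0.667 for oxidative stress, 0.919 for the unfolded protein response, 0.919 for macrophage and leukocyte markers and 0.996 for fatty acid synthesis. Fabp4 measured 0.031 ± 0.044 (adjusted p = 0.737) and Plin4, a lipid droplet protein, fell by 0.53 ± 0.058 (adjusted p = 0.0123). The gene count was 199 and 228 without control 3 h replicate 1 and 2, 109 and 186 without knockdown 3 h replicate 1 and 2, and 357 and 513 without knockdown 6 h replicate 1 and 2. Without control 6 h replicate 1 it was 1175, with 607 higher and 568 lower, and without control 6 h replicate 2 it was 2000, with 1019 and 981. Of the 60 genes named by rule that passed, 31 passed without each array in turn; of those printed here Clec14a, Smad9, Otop1, Lhx3, Kiss1, Ano2, Kcne1, Trhr2, Mgll and Plin4 did not, at adjusted p up to 0.169 (Trhr2). The prostaglandin and heat shock lists lost their calls without control 6 h replicate 1 (camera adjusted p = 0.0875 and 0.0579) and the chemokines without control 6 h replicate 2 (0.0550). The prostaglandin list lost it too without control 3 h replicate 2 (0.0613) or knockdown 6 h replicate 2 (0.0792).

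The comparison of the effect at 6 h with that at 3 h asks which genes differed between the times in their response. In limma 0 genes passed, against 2272 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0660. Among named genes Saa3, Cck and Gask1a had the smallest adjusted p, 0.072 for each. Saa3 and Cck differed by 1.16 ± 0.087 and 1.32 ± 0.11, while for Gask1a no difference is given because only the control 6 h arrays were well above background. Hp measured 1.05 ± 0.095 (adjusted p = 0.115). Il6 differed by -0.015 ± 0.13 (adjusted p = 0.978), its sign changing with the scaling. The 3 h and 6 h effects share no array but share each gene's variance in the fit, so overlaps of calls were set against those expected within groups of 100 genes of like variance. Of the genes and unnamed probes, 51 were higher at both times, against 1.84 expected, and 3 were lower at both, against 0.07. That expectation does not allow for slide column, which went with supernatant at both times, or for a shared supernatant preparation. Opposite calls numbered 0, and 60 of the 63 called at 3 h had the same sign at 6 h. The Pearson correlation of the effects was 0.264 across genes, which are not independent replicates, and 0.376 over the 21624 that were above background on all arrays. The interaction count was 261 without control 6 h replicate 1, 294 without control 6 h replicate 2, 49 without knockdown 6 h replicate 2, 3 without control 3 h replicate 2 and 1 without knockdown 6 h replicate 1.

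**Figure D3:**
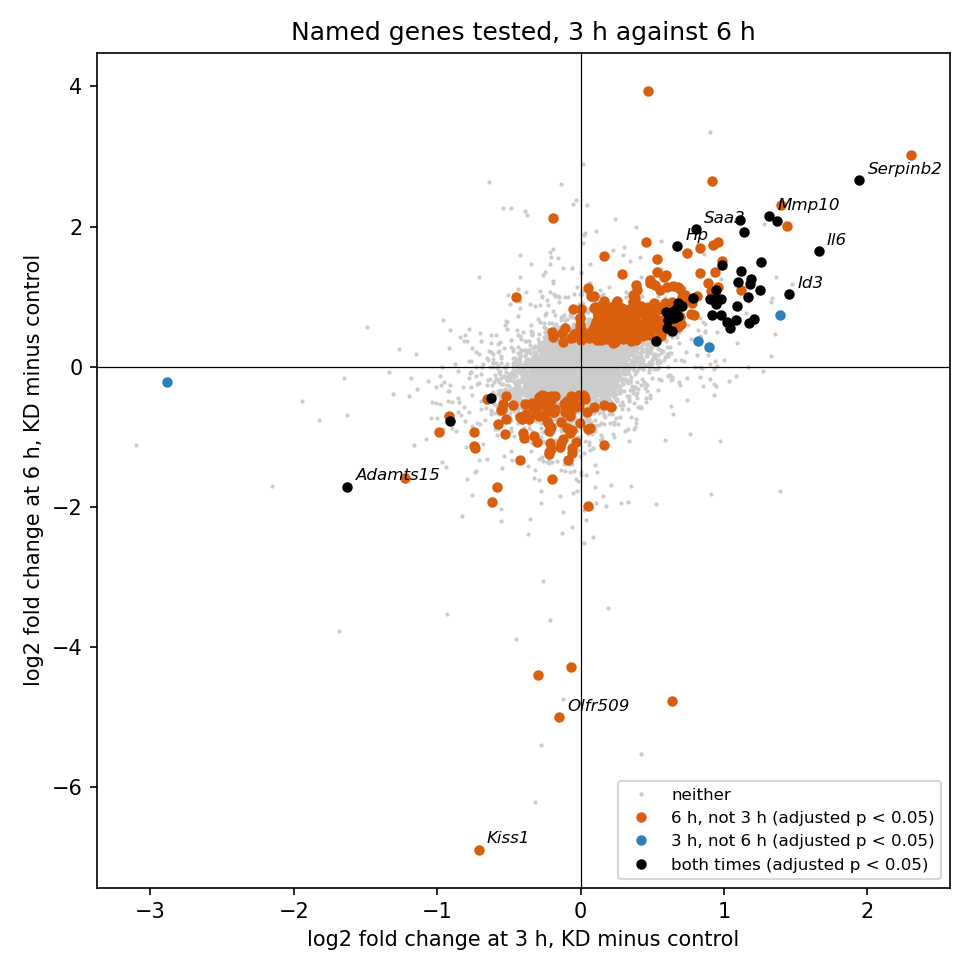
Log2 fold change of each named gene, knockdown (KD) minus control supernatant, at 3 h (horizontal axis) and 6 h (vertical axis); black points passed at both times, orange points at 6 h and not at 3 h, blue points at 3 h and not at 6 h, grey points at neither. Serpinb2, Il6 and Id3 lie at the upper right and Adamts15 at the lower left, while Kiss1 and Olfr509, drawn at fitted values of -6.90 and -5.00 at 6 h, were not well above background in the knockdown groups.

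Between 3 h and 6 h with control supernatant, immediate early and circadian clock genes were lower. Of 38 immediate early genes 24 fell and 4 rose, 25 and 5 adjusted over the list alone (median -0.90; camera adjusted p = 0.000349; adjusted p = 0.547 with an estimated correlation). Ereg fell by 2.81 ± 0.070 (SE, 2 arrays per group) and Hbegf fell by 1.85 ± 0.078, while Klf2 rose by 1.77 ± 0.075. Of 20 clock genes 14 fell, 14 adjusted over the list alone (median -0.51; camera adjusted p = 0.000349; adjusted p = 0.547 with an estimated correlation). Cry1, Per2 and Nr1d1 fell by 2.01 ± 0.11, 1.41 ± 0.080 and 1.38 ± 0.087. The zinc transporter gene Slc30a1 fell by 3.28 ± 0.067 (adjusted p = 8.40e-05), Gzmm fell by 3.12 ± 0.064, Gpd1, an enzyme of glycerol 3-phosphate metabolism, fell by 2.40 ± 0.064 and Fasn, the fatty acid synthase, fell by 1.55 ± 0.090. Celsr3 fell by 3.12 ± 0.17, and Serpinf2 fell by 3.43 ± 0.24 with 1 of 2 arrays well above background at 6 h. Nos2, the inducible nitric oxide synthase, rose by 2.31 ± 0.099 and Chac1, a glutathione-degrading enzyme, rose by 2.67 ± 0.072 (adjusted p = 8.40e-05). Il6 and Ccl2 fell by 0.74 ± 0.090 and 1.25 ± 0.087, Saa3 rose by 0.66 ± 0.061, and Usp2 (-0.31 ± 0.11, adjusted p = 0.0664), Fabp4 (-0.19 ± 0.063, adjusted p = 0.0638) and Lcn2 (-0.19 ± 0.097, adjusted p = 0.185) did not pass. The largest rises, Kiss1, Gnrhr, Dmc1, Olfr509 and Tex52 (at least 34.6-fold, 18.6-fold, 12.4-fold, 7.92-fold and 21.7-fold), had 1 or both control 6 h arrays in a bright patch, and Gnrhr, Dmc1 and Tex52 missed the threshold without 1 array or more (adjusted p up to 0.0565, 0.121 and 0.122).

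With knockdown supernatant the same pair of lists was lower at 6 h than at 3 h. Of the immediate early genes 25 fell and 2 rose, 25 and 2 adjusted over the list alone, and of the clock genes 12 fell, 13 adjusted over the list alone. Both lists had a camera adjusted p of 0.000119 (adjusted p = 0.49 with an estimated correlation). Slc30a1 fell by 3.50 ± 0.067, Ereg fell by 2.56 ± 0.070 and Per2 fell by 1.66 ± 0.080, and Chac1 and Nos2 rose by 2.49 ± 0.072 and 2.23 ± 0.099. A3galt2 fell by 3.07 ± 0.16, and Serpinf2 fell by 3.20 ± 0.24 with 1 of 2 arrays well above background at 6 h. Tbxa2r was at least 6.33-fold lower, and Lypd6b was at least 5.89-fold higher. Mirt2, Vmn1r104, Sprr2e and Tmie were at least 13-fold, 5.32-fold, 9.91-fold and 8.6-fold higher, each with 1 compared array in a bright patch, and Mirt2, Sprr2e and Tmie missed the threshold without 1 array or more (adjusted p up to 0.0933, 0.0793 and 0.156). Saa3 rose by 1.82 ± 0.061 and Lcn2 rose by 0.34 ± 0.097, Il6 and Ccl2 fell by 0.76 ± 0.090 and 0.71 ± 0.087, and Usp2 and Fabp4 fell by 0.44 ± 0.11 and 0.26 ± 0.063, calls that like that of Lcn2 were lost without 1 array or more (adjusted p up to 0.111 for Fabp4 and 0.169 for Lcn2). In limma 10293 genes and unnamed probes changed with control supernatant, 4200 higher and 6093 lower, and 10300 with knockdown supernatant, 4566 higher and 5734 lower. With median scaling the splits were 2649 higher and 9734 lower, and 3446 and 7063, and with no scaling 2869 and 2870, and 3684 and 1814, so the excess of falls depends on the scaling. The changes went the same way in both supernatants for 8174, with 3579 higher and 4595 lower against 840 and 1608 expected among genes of like variance, and opposite ways for 27. Across genes their Pearson correlation was 0.789. All 3 h arrays lay in 1 row of the slide and all 6 h arrays in the other, so time and slide position cannot be told apart. The 8 spike-in transcripts had a median of -0.38 and an SD of 0.11 between the times with control supernatant, against an SD of 0.68 over genes, and a median of -0.087 and an SD of 0.022 with knockdown supernatant, against 0.66. Without knockdown 3 h replicate 1 the knockdown count was 6704.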

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

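The list tests in this part were not among the comparisons set beforehand, and no test was chosen for a single list. Between 3 h and 6 h the effect of knockdown supernatant on 3 of the 26 lists differed by a camera test of the difference of the effects. The acute phase and IL-6/STAT3 list had a median difference of 0.24 on the log2 scale, higher at 6 h (camera adjusted p = 1.51e-06; adjusted p = 0.0984 with an estimated correlation). None of its 25 members passed in limma over all genes and 6 did adjusted over the list alone, with Saa3 at 1.16 ± 0.087 and Hp at 1.05 ± 0.095. The interferon response list had a median difference of -0.17 (camera adjusted p = 1.83e-06; adjusted p = 0.597 with an estimated correlation), with 0 members higher and 0 lower adjusted over the list alone, and Rsad2 at -0.44 ± 0.092. The ribosomal protein list had a median difference of -0.069 (camera adjusted p = 0.0361; adjusted p = 0.915 with an estimated correlation), with 0 members higher and 0 lower adjusted over the list alone. Over all genes the median difference was 0.027, and it was 0.14 with median scaling and 0.13 with no scaling. Over the 8 spike-in transcripts it was 0.26 (SD 0.12), about as large as that of the acute phase list.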

How the results depend on the processing

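The masking of bright patches was chosen after the data were examined, and the other settings before. Calls of named genes between supernatants numbered 27 at 3 h, 48 at 6 h and 60 on average, of which 0, 27 and 31 passed without each array in turn. Between the times they numbered 79 with control and 83 with knockdown supernatant, of which 72 and 74 did. The pooled counts that follow hold both kinds. Of 297 calls of named genes, 286 were kept with quantile normalization, 275 with median scaling, 201 with no scaling, 191 with no filter, 264 with normexp, 294 with the trend and robust options, 284 with array weights, 291 with the deposited log2 table and 217 to 281 without 1 array, and 0 reversed. The deposited table holds the main signal with 1 shift per array, so keeping nearly all calls with it is little of a check. Of 291 calls that could be masked, 289 were kept. With the arrays of 1 time alone 0 of 75 were kept. Of 32 list calls, 9 were kept with an estimated correlation and 27 to 32 without 1 array. Slide as a block was not run because there was 1 slide. Normexp used the median spot signal, the mean not being used here. A lone array left in a group was assumed to vary like the other groups. Signal over background limits the dim genes, of which 94 were among the 593 calls at 6 h. The cause of each change below was not tested.

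For 63 genes at 3 h, the count was 126 with normexp, 25 with median scaling, 0 with no scaling (1296 at an unadjusted p under 0.05 in limma), 0 with no filter (3128 unadjusted), 193 with probes above background on all arrays, 354 with trend and robust options, 310 with array weights, 0 with the arrays of that time (3574 unadjusted), 236 at an adjusted p under 0.10, and 0 to 35 without 1 array. For 593 genes at 6 h it was 1075 with median scaling, 96 with no scaling, 18 with no filter, 1308 with trend and robust options, 194 with array weights, 0 with the arrays of that time (3044 unadjusted), 1305 at 0.10, and 144 to 1955 without 1 array. For 807 genes on average it was 1220 with median scaling, 150 with no scaling, 76 with no filter, 1580 with trend and robust options, 1751 at 0.10, 281 with a 1.5-fold minimum, and 109 to 2000 without 1 array. For 0 genes in the difference of effects it was 5 with normexp, 11 with quantile normalization, 1 with median scaling, 11 with no scaling, 4 with probes above background on all arrays, 16 with trend and robust options, 8 at 0.10, 3 with bright patches masked, and 0 to 294 without 1 array. For time it was 5739 and 5498 (control and knockdown) with no scaling, 5932 and 5663 with a 1.5-fold minimum, and 7196 to 10363 and 6704 to 11862 without 1 array. Median scaling moved the median over all genes to 0.19 at 6 h, 0.12 on average, -0.27 for time with control and -0.20 with knockdown supernatant, so that changes under it are relative to that shift. With no filter it was -0.16 at 6 h.

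The Pearson correlation of the effects, 0.264, was 0.327 with normexp, 0.167 with no filter, 0.376 with probes above background on all arrays, 0.309 with bright patches masked, and 0.206 to 0.270 without 1 array. The list counts with an estimated correlation were 4 at 3 h, 1 at 6 h, 4 on average and 0 for time with control supernatant, and without 1 array 9 to 10, 6 to 11, 8 to 11 and 2 to 3. For time the 2 lists became 5 with quantile normalization, 7 with no filter, 4 with each probe alone, 6 at 0.10 and 18 with fry.

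Reversed values all belonged to genes that had not passed. Fabp4 at 6 h was 0.012 with normexp, 0.18 with median scaling, 0.040 with no scaling, 0.018 with the deposited table and -0.024 to 0.011 without 1 array, and on average -0.0073 with quantile normalization. Its difference of effects was 0.034 with median scaling and 0.025 with no scaling. Usp2 at 6 h was 0.12 with quantile normalization, 0.18 with median scaling, 0.043 with no scaling, 0.020 with the deposited table and -0.076 to 0.069 without 1 array, and on average -0.020 with normexp. The Il6 difference of effects was 0.12 with quantile normalization, 0.094 with median scaling, 0.084 with no scaling, 0.0024 with the deposited table and -0.11 to 0.080 without 1 array. With median scaling Psmb9 at 6 h was 0.0017 and Phgdh on average 0.028.

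Replicate numbers were not shown to pair the samples: correlations of replicate differences between groups lay between -0.047 and 0.087. With the replicate number as a block, limma called 0 genes at 3 h (2766 at an unadjusted p under 0.05), 223 at 6 h and 510 on average.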

Other observations

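The tests of slide position, supernatant preparation, array sensitivity, single probes and bright patches were chosen only after the results were seen, and the counts over other splits of the arrays were set before. Among calls averaged over both times, the clock genes Dbp, Arntl and Nfil3 measured -0.55 ± 0.054, 0.45 ± 0.072 and 0.38 ± 0.064 (SE, 4 arrays per supernatant; limma adjusted p = 0.00895, 0.0364 and 0.043), in a list that did not pass. All 3 missed the threshold without 1 array or more, at adjusted p up to 0.0592, 0.152 and 0.162. The preadipocyte transcription factors Zfp423 and Gata3 fell by 0.57 ± 0.067 and 0.29 ± 0.049 (adjusted p = 0.0151 and 0.044, up to 0.0842 and 0.169 without 1 array). Ddit3, a stress response factor, fell by 0.38 ± 0.052, the glutathione transferase Gsta3 fell by 0.46 ± 0.079 and Acacb, an acetyl-CoA carboxylase, fell by 0.26 ± 0.046, at adjusted p up to 0.107, 0.169 and 0.178 without 1 array. Vegfa and Cd14 were higher by 0.40 ± 0.057 and 0.47 ± 0.058, and the prostaglandin receptor Ptgfr fell by 0.54 ± 0.075, at adjusted p up to 0.125, 0.0862 and 0.105 without 1 array.

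The numbers of genes and lists called in either direction for the average were set against other splits of the 8 arrays. With time as a covariate the real split called 538 genes. Of 34 splits 1, the real one, reached that count, the highest other being 0. Some of the other splits did not hold 2 arrays of each time on each side, as the real one did. The other splits also count the effect of the supernatants as spread between arrays, so this does not exclude chance for the number of genes. For lists 2 of 34 splits reached 10, the highest other also 10, so chance cannot be excluded for their number. At a camera adjusted p under 1e-6, a limit not set before, the real split called 4 lists and the highest other 3. The 16 splits that kept 3 of 4 arrays of each arm together called 3 to 10 lists, and the 17 that kept 2 called at most 2. For the rise of immediate early, acute phase, NF-kB and TGF-beta genes, slide column or hybridisation cannot be told apart from the supernatant, since 0 slide columns held arrays of both. The 8 spike-in transcripts had a median of -0.088 at 3 h and 0.15 at 6 h (SD 0.032 and 0.10), beside TGF-beta list medians of 0.14 and 0.17. A single supernatant preparation per arm cannot be told apart from the knockdown, since 0 of the labels name a preparation.

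Among adipocyte markers, 11 of 40 (27.5%) were not well above background on any array, against 25.5% of all named genes. The 95% interval of that share, 14.6% to 43.9%, includes that of all named genes. This cannot decide on low sensitivity of the arrays, since all named genes include genes that these cells may not express. Failed probes cannot be told apart, since 2 of the 11 undetected genes, Cidec and Adrb3, had over 1 probe. No biological explanation was tested.

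Of 29 genes and unnamed probes at least 4-fold lower at 6 h, 22 were detected on control 6 h arrays alone, and 18 of these lay in a bright patch, against 6.64% of all tested. Spots around the 22 had a median log2 excess of 1.54 on the brighter control array, against 0.174 over all tested, in line with bright patches as a cause. Ano2 and Olfr67 still passed with the patches masked (adjusted p = 0.00620 and 0.00588), on 1 control 6 h array each. Spots around that array's spot had a median log2 excess of 0.0627 for Ano2 and 0.475 for Olfr67, just under the limit for a patch, so for Olfr67 the masked call does not speak against patches. Of the 22, 4 lay outside any patch. No biological explanation was tested for the 22.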
